A study of Mus musculus with 18 samples.

How the data were processed

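The series measured RNA of mouse retina on Affymetrix expression arrays in 6 groups: mice without Rpe65 and C57BL/6 controls, each sampled at ages of 2, 4 and 6 months, with 3 retinas per group and 18 arrays in all. The deposited values covered 45101 probe sets, with 1 value per probe set and array. The deposited values were on a linear scale and in the unit ratio. The submitters' processing notes named RMA for 18 samples and GCOS for 16 of them, with no version and no order of steps. The values themselves were not on the scale that RMA gives, so the step that summarised probes to probe sets was not settled. In 54.3% of probe sets the median over the 18 arrays was 1 (within 1e-05), and in the other 45.7% it lay below 1. In the latter, each array's values were whole multiples of 1 step per array (within 0.02 of a step, for 100% of the values checked). The values were therefore read as signals in steps of 0.1, divided by a factor per array and then by the probe set's own median, or by 1 fixed divisor where that median was lower. Values below 0.01 had been set to 0.01, which held for 0.0244% to 0.630% of values per array. Probe sets with the fixed divisor are called dim below: their median spread within groups was 1.16 on the log2 scale, against 0.25 in the others. The number of arrays limits the precision of every value.

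Gene names came from the platform annotation that accompanied the values. Of the probe sets, 64 control sets were left out, 34945 named 1 gene, 932 named several and 9160 named none. A gene was measured by the probe set with the highest mean array-scaled signal among those that named it alone, which gave 18193 genes, 9010 of them with more than 1 probe set. Gene identifiers led to 0 updated symbols. No exon coordinates of probes were used, so no position within a gene is given.

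The log2 of the ratios was tested with limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 6 groups, which left 12 residual degrees of freedom, and moderated two-sided tests were adjusted with Benjamini-Hochberg over all genes of a contrast, with 0.05 as the threshold. The contrasts were knockout against control at each age, their mean over the 3 ages, the differences of that effect between ages (a moderated F-test on 2 contrasts), and 6 against 2 months within each genotype. The comparisons of 4 against 2 months were added later. Errors given with log2 fold changes are standard errors of this fit, and errors given with ratios are SDs over 3 arrays.

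Named genes followed a rule. Rpe65 came first. For knockout against control at each age and over the mean of the ages, the 10 largest rises and the 10 largest falls were taken among genes past the threshold whose 3 knockout arrays all lay on 1 side of the 3 controls (at every age, for the mean). For comparisons of ages, the 5 largest in each direction were taken. Names of gene models without a symbol were passed over. Members of gene lists could be named with their list. The lists covered rod, cone and shared photoreceptor genes, the visual cycle, pigment epithelium and melanocytes, rod and ON bipolar, OFF bipolar, horizontal, amacrine and ganglion cells, Müller glia, gliosis and stress, microglia, antigen presentation, interferon response, apoptosis, immediate early genes, antioxidant defence, cholesterol synthesis, glycolysis, oxidative phosphorylation, the circadian clock, lens, blood, vessels, connective tissue, muscle, corneal epithelium, and Y-linked genes and Xist. Lists of at least 3 measured genes were tested with camera at its preset correlation of 0.01, adjusted over the lists. They were tested again with an estimated correlation, on ranks, and with fry. The groups, the tests, the rule for named genes, the gene lists and 18 of the alternatives, besides leaving out each of the 18 arrays in turn, were chosen before the data were examined.

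Sex, which the labels did not give, was read from Xist and Y-linked genes. Array quality was read from the spike-in control probe sets and from the 5' and 3' probe sets of actin and Gapdh. The fits were tested on simulated data with the spread of the real arrays and 200 changed genes among 18193. Of genes changed 2-fold, 36% were recovered at 4 months and 62.5% over the mean of the ages, and 89.6% of the latter among probe sets that were not dim. Of 2-fold differences in effect between ages, 15.5% were recovered. Other software was the R package data.table in version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

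The alternatives tried were a filter on the dimmest 40% of genes, the mean of all probe sets of a gene, leaving out probe sets open to cross-hybridisation, quantile normalization, centring of arrays, only the 6 arrays compared, a trended and robust prior, array weights, a 1.5-fold minimum, the Benjamini-Yekutieli adjustment, covariates for lens, pigment epithelium and sex, leaving out the chromosome of Rpe65, log2(signal + 16) on the recovered array-scaled signals (the ratios themselves lie near 1), other list tests, and each array left out in turn. A further 6 were chosen after seeing the data.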

Results

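Retinas of mice lacking Rpe65, the retinoid isomerase of the retinal pigment epithelium that regenerates the visual chromophore, were profiled beside retinas of C57BL/6 controls at 2, 4 and 6 months. The question was which retinal transcripts differ after loss of Rpe65 and whether the difference depends on age. Each of the 6 groups held 3 arrays, 1 per retina. Median array signal before scaling was 6.80 to 14.3 at 2 and 4 months and 32.8 to 45.8 at 6 months, in both genotypes, so that age 6 months cannot be told apart from that difference between arrays, while genotypes were compared within an age. Arrays of a group correlated across the genes above the median signal with Pearson's r of 0.935 to 0.981, where genes are not independent replicates. Xist and Y-linked genes marked 8 male and 1 female retinas among the knockouts, and 3 male and 6 female among the controls. The log2 ratio of Xist was 5.11 to 5.50 in the female and -2.76 to 0.48 in the male retinas.

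Rpe65 transcript was lower in knockouts at 2 and 6 months and over the mean of the ages. Its ratio in knockout retinas was 0.0433, 0.111 and 0.0542 at 2 months, 0.780, 0.394 and 0.815 at 4 months and 0.156, 0.0348 and 0.0828 at 6 months. In controls it was 33.9, 0.609 and 1.74 at 2 months, 2.49, 15.8 and 46.7 at 4 months and 12.5, 17.5 and 27.7 at 6 months. Over the mean of the ages it was lower (log2 -5.96 ± 0.73, adjusted p = 0.000177, lower in all 9 knockout arrays than in the 3 controls of their age). At single ages the log2 difference was -5.69 ± 1.26 (adjusted p = 0.0424), -4.28 ± 1.26 (adjusted p = 0.157, not past the threshold) and -7.89 ± 1.26 (adjusted p = 0.00635). The knockout signals lay below the array's median signal in all 9 arrays, so that the size of the fall is not fixed by these values (-3.03 with log2(signal + 16)). The probe set is dim, and controls differed among themselves. The 3 controls of lowest Rpe65 ratio, retinas 11, 9 and 14, also had the lowest mean log2 pigment epithelium signal among controls. It was -3.39, -3.36 and -1.56 there and -0.95 to 0.08 in the other controls. Which part of the gene the probe set reads, relative to the part deleted, is not known.

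**Figure D1:**
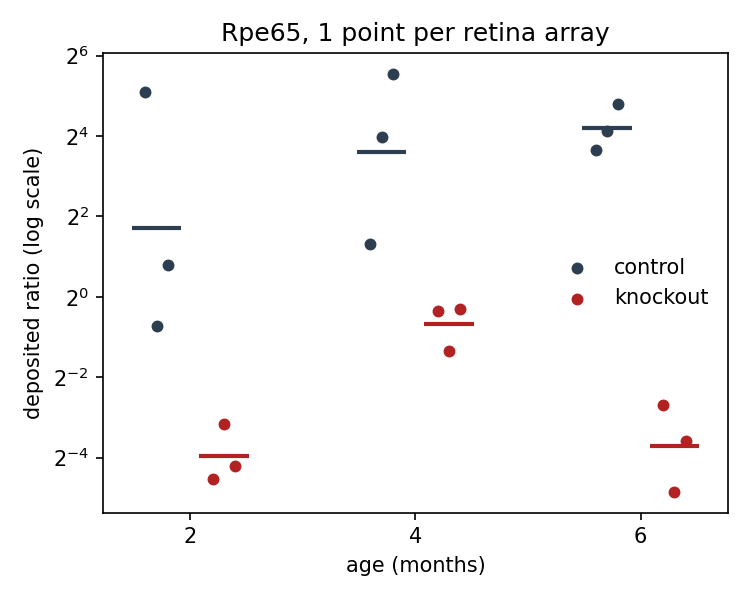
Deposited ratio of Rpe65 on a log scale against age in months, 1 point per retina array, with the bar at the geometric mean of 3 arrays. Control retinas ranged from 0.609 to 46.7 and knockout retinas from 0.0348 to 0.815.

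Cone photoreceptor genes were lower in knockouts over the 3 ages: of 13 measured, 9 fell and 1 rose (also 9 and 1 adjusted over the list alone). Opn1sw, the short-wavelength cone opsin, was lower (log2 -4.65 ± 0.14, 9 knockout and 9 control arrays, adjusted p = 6.64e-10; -3.32 by a further probe set). Its ratio at 2 months was 3.12 ± 0.49 (SD, n = 3) in controls and 0.260 ± 0.050 in knockouts, and at 6 months 2.33 ± 0.55 and 0.0534 ± 0.0125. The cone phosphodiesterase subunits Pde6c (log2 -2.19 ± 0.15) and Pde6h (-1.79 ± 0.12), cone arrestin Arr3 (-1.89 ± 0.14), cone transducin Gnat2 (-1.61 ± 0.10) and the potassium channel subunit Kcne2 (-1.41 ± 0.10) fell as well. Opn1mw, the middle-wavelength opsin, fell less (-1.11 ± 0.19), as did the channel subunit Cngb3 (-0.77 ± 0.18) and Gngt2 (-0.61 ± 0.16). Gnb3, which is also expressed in ON bipolar cells, rose (0.54 ± 0.13), but 0 cone genes passed as higher with sex as a covariate, on the ratios or on log2(signal + 16). Thrb (0.10 ± 0.23), Rxrg (-0.24 ± 0.14) and Slc24a2 (-0.10 ± 0.15), a pair of cone transcription factors and an exchanger, did not pass. The list's median was -1.11 (-0.73 with the sex covariate on log2(signal + 16)), and its adjusted p was 8.66e-14 with the preset and 0.0111 with the estimated correlation, the only list past the threshold in both.

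**Figure D2:**
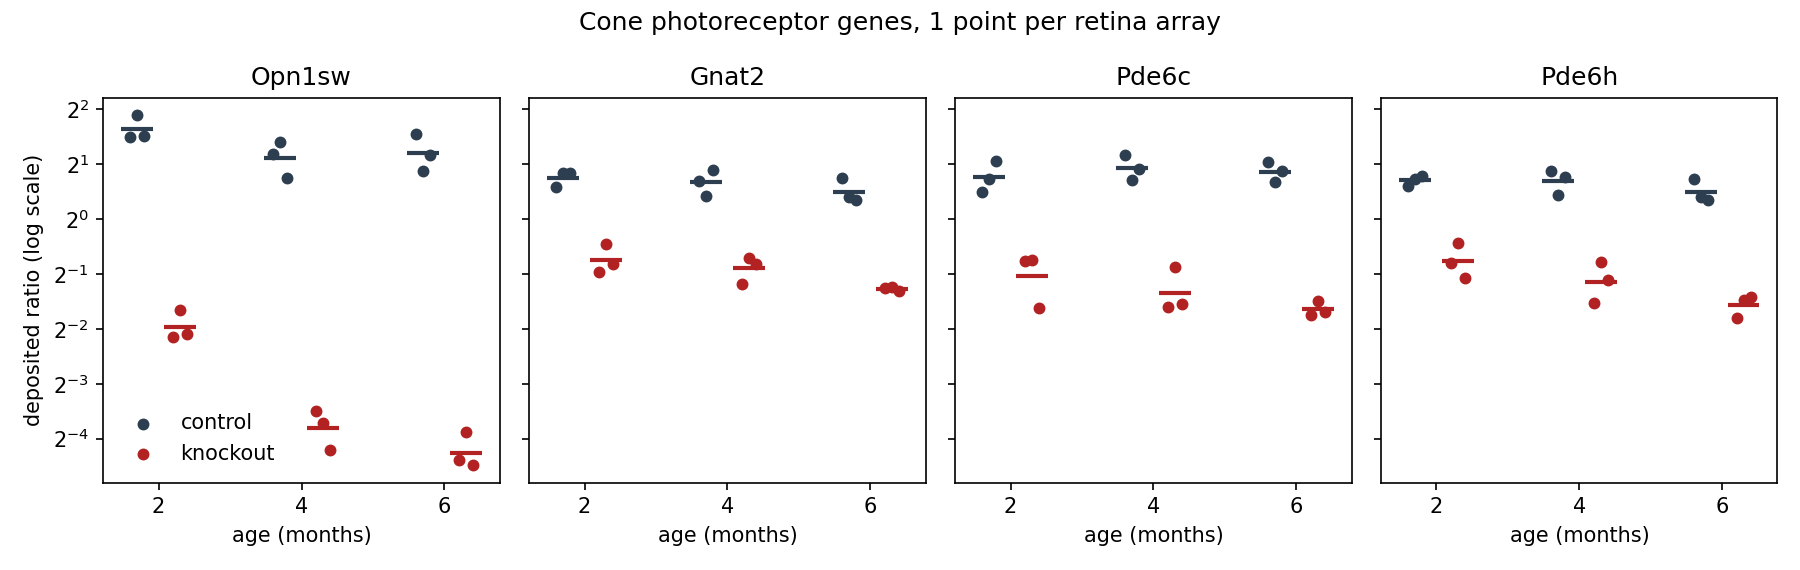
Deposited ratios of 4 cone genes on a shared log axis against age in months, 1 point per retina array, with the bar at the geometric mean of 3 arrays. Opn1sw lay at 1.68 to 3.68 in controls and 0.0448 to 0.317 in knockouts, and Gnat2 at 1.27 to 1.85 and 0.405 to 0.728.

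Rod genes were lower by smaller amounts. Of 14 measured, 9 fell and 1 rose (12 and 1 adjusted over the list alone). Reep6 (log2 -0.68 ± 0.08), the nuclear receptor Esrrb (-0.58 ± 0.12), the rod transcription factor Nrl (-0.40 ± 0.07), the outer segment protein Rom1 (-0.38 ± 0.07) and the rod phosphodiesterase Pde6b (-0.33 ± 0.06) were lower over the mean of the ages, and the transducin subunit Gnb1 was higher (0.48 ± 0.07; 2.95 by a further probe set). The list's median was -0.32, with an adjusted p of 3.61e-08, and adjusted p = 0.309 with an estimated correlation. Of 25 genes shared by rods and cones, 8 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of -0.26, an adjusted p of 3.16e-06 and adjusted p = 0.343 with an estimated correlation. The retinoid-binding protein Rbp3 (-0.62 ± 0.09), the guanylate cyclase activator Guca1b (-0.53 ± 0.07; -2.26 by a further probe set) and the transcription factor Crx (-0.52 ± 0.08; -0.20 by a further probe set) fell, while the photoreceptor kinase Grk1 rose (1.86 ± 0.21). With sex as a covariate, 7 cone, 6 rod and 6 shared genes passed as lower, and with arrays of 1 sex per age, an alternative chosen after seeing the data, 7, 2 and 3, with medians of -0.87, -0.37 and -0.26.

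Of 20 measured gliosis and stress genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone). Edn2, an endothelin made by stressed photoreceptors, was higher (log2 3.13 ± 0.40, adjusted p = 0.000265; 2.29 with log2(signal + 16)), with a ratio at 4 months of 2.21 ± 0.84 (SD, n = 3) in knockouts and 0.197 ± 0.071 in controls. The growth factor Fgf2 (2.27 ± 0.38; 1.18 with log2(signal + 16)), the oncostatin receptor Osmr (1.07 ± 0.22), Cebpd (1.11 ± 0.25), Cd44 (0.89 ± 0.19) and Stat3 (0.73 ± 0.09) rose. Gfap, an intermediate filament of reactive glia, did not pass at 1.05 ± 0.31 (adjusted p = 0.0672). Its ratio at 4 months was 0.963 to 1.66 in knockouts and 0.287 to 0.482 in controls, but at 2 months control retina 9 had 2.32, above the knockouts (0.963 to 1.32). Control retina 3 at 6 months stood apart from the other 2 controls of its age in Edn2 (0.864 against 0.0891 and 0.0833), Gfap (1.58 against 0.460 and 0.397) and Fgf2 (1.05 against 0.319 and 0.580). Its mean log2 microglia signal was 0.40, while that of all other arrays was below 0. The list's median was 0.55 (0.27 with log2(signal + 16)), with an adjusted p of 5.89e-06, and adjusted p = 0.309 with an estimated correlation. Of 12 Müller glia genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone): the potassium channel Kcnj10 (0.74 ± 0.13), the water channel Aqp4 (0.57 ± 0.11) and Apoe (0.52 ± 0.11). The list's median was 0.33, with an adjusted p of 5.89e-06, and adjusted p = 0.224 with an estimated correlation. With sex as a covariate 4 gliosis and 3 Müller glia genes passed as higher, and with 1 sex per age 1 and 1, with medians of 0.72 and 0.47. The log2 difference between 5' and 3' actin probe sets was -0.43 in 1 control at 2 months and -0.51 in 1 control at 4 months, both below the other arrays. The former, retina 11, was the only male control at 2 months and had the lowest median signal (6.80). Its mean spike-in ratios were 1.69 to 1.86, against 0.66 to 1.13 in the other arrays at 2 and 4 months. Arrays at 6 months had 1.60 to 2.91.

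Among metabolic lists, 6 of 15 glycolysis genes fell and 0 rose (also 6 and 0 adjusted over the list alone), led by hexokinase Hk2 (log2 -1.19 ± 0.10) and phosphofructokinase Pfkp (-0.40 ± 0.08). The list's median was -0.13 (-0.07 without the 2 controls of low actin signal), with an adjusted p of 0.000134, and adjusted p = 0.473 with an estimated correlation. Of 17 antioxidant genes, 2 rose and 0 fell (also 2 and 0 adjusted over the list alone): glutathione reductase Gsr (1.04 ± 0.07; 0.39 by a further probe set) and the peroxiredoxin Prdx4 (0.55 ± 0.14; 0.06 by a further probe set). That list had a median of 0.19, an adjusted p of 0.00248 and adjusted p = 0.473 with an estimated correlation. Of 15 immediate early genes, Fos (-0.92 ± 0.11) and Nr4a1 (-1.16 ± 0.16) fell and 0 rose (3 and 0 adjusted over the list alone), with a median of -0.21 (-0.08 with log2(signal + 16) and -0.44 with sex as a covariate), an adjusted p of 0.0182 and adjusted p = 0.309 with an estimated correlation. With sex as a covariate 2 glycolysis and 2 immediate early genes passed as lower and 1 antioxidant gene as higher, and with 1 sex per age 1, 2 and 1.

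**Figure D3:**
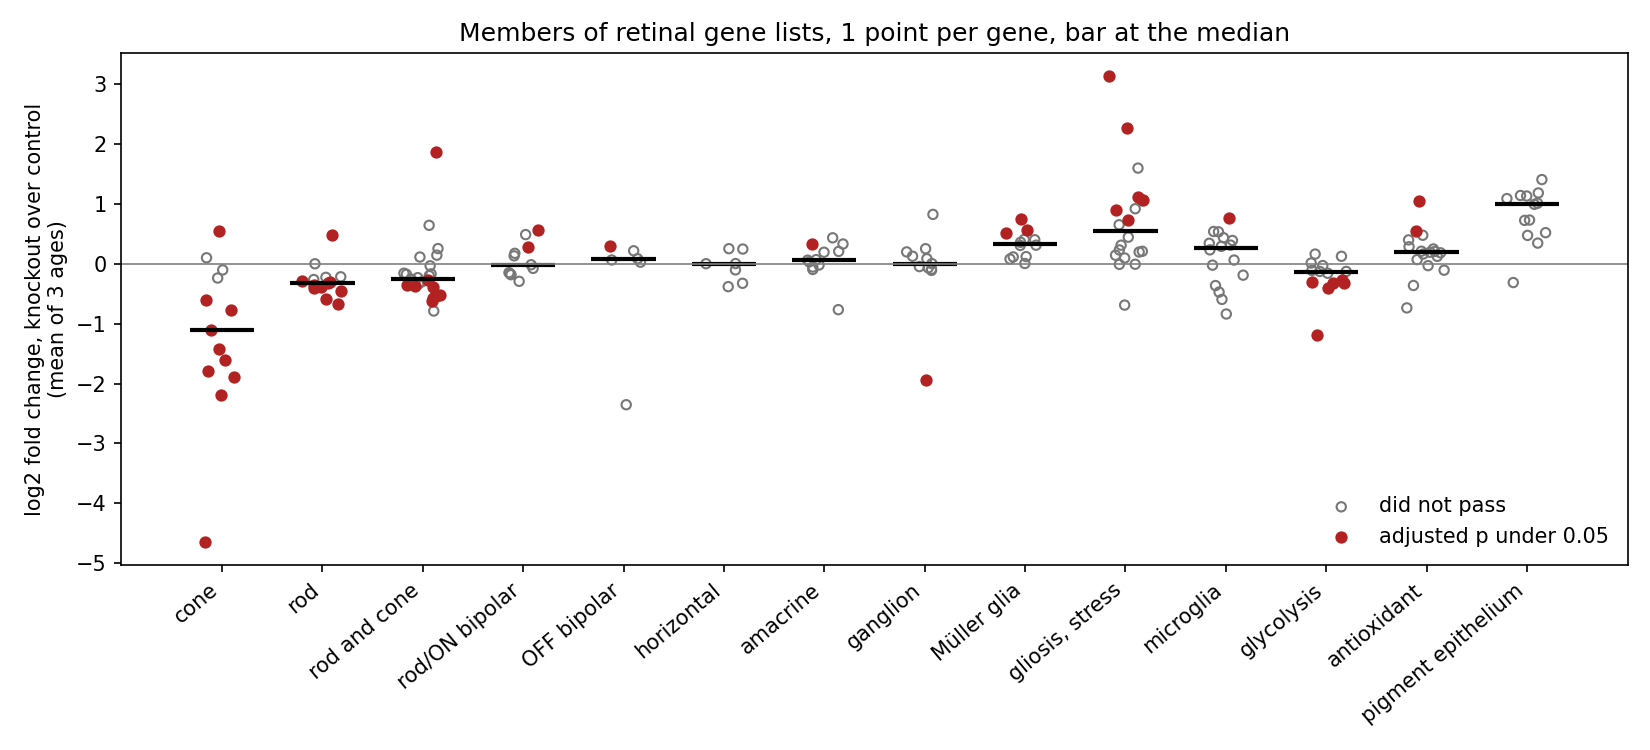
Log2 fold change of knockout over control, mean of 3 ages, for members of 14 gene lists, 1 point per gene, filled where the adjusted p lay under 0.05, with the bar at the list's median. The cone median lay at -1.11, the rod median at -0.32 and the Müller glia median at 0.33.

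Lists of neighbouring tissues differed between genotypes at the preset correlation only. The pigment epithelium list (13 genes, 0 rose and 0 fell, 1 and 0 adjusted over the list alone) had a median of 0.99 (0.41 without the 2 controls of low actin signal, 0.55 with log2(signal + 16) and 1.64 with sex as a covariate), an adjusted p of 0.00285 and adjusted p = 0.649 with an estimated correlation. Of its genes, 5 passed as higher with the sex covariate on log2(signal + 16) and 2 with the sex covariate. Arrays of 1 sex per age kept only control retina 11 at 2 months, which had the lowest mean log2 pigment epithelium signal of all arrays (-3.39). The lens list (17 genes, 0 rose and 0 fell, also 0 and 0 adjusted over the list alone) had a median of -2.13 (-0.99 with log2(signal + 16)), an adjusted p of 0.00285 and adjusted p = 0.874 with an estimated correlation. Mean log2 lens signal ranged from -4.11 to 5.22 among knockouts at 2 months alone. In controls of all ages it ranged from -2.73 to 2.36. Control retina 1 at 6 months (2.36) thus lay above knockout retina 2 at 2 months (1.51). The alternative without 2 knockouts of high lens signal removed no control. The 3 Y-linked genes had a median of 2.27 (0.96 with log2(signal + 16) and -0.38 with sex as a covariate), an adjusted p of 0.0365 and adjusted p = 0.530 with an estimated correlation, beside the sex counts above, with 0 rising or falling over all genes and 1 rising adjusted over the list alone.

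Over the mean of the ages, 1022 of 18193 genes passed, 453 higher and 569 lower in knockouts. The largest rises were in the angiotensin receptor Agtr1a (log2 5.09 ± 0.40), the phosphodiesterase family member Gdpd3 (4.77 ± 0.47), Iqcm (4.51 ± 0.52) and the transcription factor Sox30 (4.24 ± 0.43), followed by Edn2, Fgf2os (2.53 ± 0.40), Ap1s3 (2.32 ± 0.60), the ciliary gene Cfap54 (2.30 ± 0.10), Fgf2 and the acetyltransferase Nat1 (2.24 ± 0.23). Fgf2os is named for the strand opposite Fgf2. After Rpe65, the largest falls were in Hdc, the enzyme that makes histamine (-4.98 ± 0.33), Opn1sw, Mir1931 (-4.47 ± 0.58), the meiotic cohesin Rec8 (-4.02 ± 0.56), the long noncoding RNA Rmst (-3.19 ± 0.39), the zinc finger genes Zfp874a (-2.85 ± 0.48) and Zfp429 (-2.78 ± 0.60), the cholecystokinin receptor Cckbr (-2.81 ± 0.60) and Abhd14a (-2.74 ± 0.10). Iqcm, Ap1s3, Mir1931, Rec8, Zfp874a and Zfp429 were read by dim probe sets. The sizes and ranks of many of these folds rest on low signals: with log2(signal + 16) Agtr1a had 1.92, Gdpd3 2.59, Iqcm 1.04, Sox30 2.20, Hdc -2.52 and Mir1931 -0.84, while Opn1sw had -4.04 and Abhd14a -2.48. In 468 of the 1022 genes the 3 knockouts lay beyond the 3 controls at every age. Over all 18193 genes 489 (2.69%) were separated in that way, where chance gives 0.025%. With sex as a covariate 574 genes passed, 494 of them shared, and with arrays of 1 sex per age 377 passed. Removing the 2 knockouts of high lens signal gave 618 and a pigment epithelium covariate 650.

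At 2 months, 260 genes passed, 101 higher and 159 lower. Beyond the genes above, the largest rises were in the mucin-like Glycam1 (log2 4.65 ± 0.95), Tbc1d21 (3.85 ± 0.86), the succinate receptor Sucnr1 (3.54 ± 0.75), the lymphoid transcription factor Ikzf3 (2.84 ± 0.50) and the spindle protein Prc1 (2.62 ± 0.56), all dim. Iqcm (6.32 ± 0.91), Sox30 (5.25 ± 0.75), Agtr1a (4.81 ± 0.69), Fgf2 (3.29 ± 0.66) and Nat1 (3.12 ± 0.40) completed the leading 10. The largest falls were Hdc (-6.04 ± 0.58), Rpe65, Rmst (-4.90 ± 0.67), the integrin Itga1 (-4.15 ± 0.64, dim), Opn1sw (-3.59 ± 0.25), the galactosidase-like Glb1l3 (-3.41 ± 0.32), Fxyd6 (-3.18 ± 0.30), the apolipoprotein Apoa4 (8.02-fold lower, dim), the motor protein Myo7a (-2.75 ± 0.31) and Odf4 (-2.75 ± 0.61, dim). A fit of only the 6 arrays of this age called 36 genes. The count was 71 without the 2 knockouts of high lens signal, 165 without the control of low actin signal at this age and its counterpart at 4 months, 151 with sex as a covariate and 130 with males alone, which leaves 1 control, that of low actin signal.

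At 4 months, 222 genes passed, 106 higher and 116 lower. Agtr1a (log2 5.62 ± 0.69), Gdpd3 (5.25 ± 0.82), Fgf2os (3.59 ± 0.69), the vomeronasal receptor Vmn1r14 (3.57 ± 0.60, dim), Edn2 (3.48 ± 0.69) and Sox30 (3.44 ± 0.75) led the rises, with Cfap54 (2.56 ± 0.17), the peptide hormone Apela (2.24 ± 0.28), Cuedc1 (2.17 ± 0.12) and the kinase Alpk2 (2.10 ± 0.39). Over the mean of the ages, a further probe set of Cuedc1 gave -0.12 against 2.13, and 1 of Apela 1.03 against 1.82. The falls were led by securin, Pttg1 (-5.69 ± 0.36), Opn1sw (-4.91 ± 0.25), Rec8 (-4.56 ± 0.97), Hdc (-4.45 ± 0.58), the lymphatic growth factor receptor Flt4 (-3.24 ± 0.34), the amino acid oxidase Dao (-2.76 ± 0.60, dim), Fxyd6 (-2.61 ± 0.30), Abhd14a (-2.57 ± 0.17), Dleu7 (-2.43 ± 0.39) and the taste receptor Tas1r1 (-2.41 ± 0.46, dim). A fit of only the 6 arrays of this age called 10 genes and males alone gave 99. A pigment epithelium covariate gave 136, while the dim filter gave 364.

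At 6 months, 203 genes passed, 73 higher and 130 lower. Gdpd3 (log2 5.74 ± 0.82), Agtr1a (4.85 ± 0.69), Sox30 (4.03 ± 0.75) and Edn2 (3.20 ± 0.69) again had the largest rises, followed by the sperm channel subunit Catsperg2 (3.12 ± 0.68, dim), the amidating enzyme Pam (2.35 ± 0.32), the peptidase Trhde (2.32 ± 0.29), Ugt2b36 (2.20 ± 0.41, dim), Tmem26 (2.19 ± 0.33) and Cfap54 (2.10 ± 0.17). Of these, Gdpd3, Agtr1a, Sox30 and Cfap54 lay below the array's median signal in all 9 controls of the 3 ages. Their sizes and ranks at each age rest on low control signals. After Rpe65, the falls were led by Opn1sw (-5.45 ± 0.25), Mir1931 (-5.02 ± 1.01), Hdc (-4.45 ± 0.58), Igf1os (-3.17 ± 0.55, dim), Rasl11a (-3.11 ± 0.44, dim), Abhd14a (-2.94 ± 0.17), Mns1 (-2.91 ± 0.50, dim), Zfp39 (-2.58 ± 0.54) and Pde6c (-2.50 ± 0.25). A fit of only the 6 arrays of this age called 26 genes, and females alone, with 1 knockout, gave 37. The count was 112 with a lens covariate and 124 with sex as a covariate.

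The 3 ages shared 101 genes, 37 higher and 64 lower at all of them. Pairs of ages shared 127, 121 and 128 genes, each in the same direction, where independent lists would share at most 1.14 per direction. Across genes, effects at different ages correlated with r of 0.15 to 0.21 over all genes and 0.59 to 0.73 over those above the median signal, where genes are not independent replicates.

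The knockout effect differed between ages for 1 gene, Pttg1 (adjusted p = 0.00345). The unadjusted p lay under 0.05 for 831 of 18193 genes, fewer than the share of 0.05 that chance gives. The knockout effect on Pttg1 was log2 -1.26 at 2 months, -5.69 at 4 months and -0.59 at 6 months. The cause of this dependence on age was not tested. Over the mean of the ages Pttg1 had -2.51, and -1.94 by a further probe set. The ratio in knockouts was 0.424 ± 0.026 (SD, n = 3) at 2 months, 0.0280 ± 0.0198 at 4 months and 0.984 ± 0.274 at 6 months, while single controls lay between 0.977 and 1.66. The difference between the effects at 4 and 2 months was -4.43 ± 0.50. Without the 2 controls of low actin signal 0 genes passed, although that difference stayed at -4.31 ± 0.60.

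With age, 15 genes passed in controls at 6 against 2 months, 10 higher and 5 lower. They included Vmn1r14 (log2 3.59 ± 0.60), Ikzf3 (3.09 ± 0.50), the ubiquitin ligase Neurl1b (3.03 ± 0.48), the peptidase Dpp4 (2.22 ± 0.30) and Agfg2 (2.15 ± 0.35) among the rises. Irx4 (-1.97 ± 0.26), the deiodinase Dio2 (-1.93 ± 0.20), Atpsckmt (-1.64 ± 0.26), the kinase Dyrk1a (-0.68 ± 0.11) and Scmh1 (-0.67 ± 0.11) fell. In knockouts Vmn1r14 (2.18 ± 0.60), Neurl1b (2.05 ± 0.48) and Dyrk1a (-0.54 ± 0.11) changed the same way without passing. All but Agfg2, Dio2, Dyrk1a and Scmh1 of the 10 genes named first were dim. The interval between 6 and 2 months also separates the arrays of higher signal from the rest. At 4 against 2 months limma passed 0 genes in controls, with 892 of 18193 at an unadjusted p under 0.05, fewer than the share of 0.05 that chance gives.

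In knockouts 18 genes passed at 6 against 2 months, 12 higher and 6 lower. Glb1l3 (log2 2.93 ± 0.32), the phospholipid transfer protein Pltp (2.02 ± 0.34), Rab37 (1.35 ± 0.21), the anion exchanger Slc4a2 (1.25 ± 0.20) and Azin2 (1.15 ± 0.20) rose. Rasl11a (-2.85 ± 0.44), Cldn10 (-2.49 ± 0.41), Opn1sw (-2.29 ± 0.25), Zfp772 (-2.20 ± 0.24) and the ciliary gene Lca5 (-0.80 ± 0.13) fell, with Rasl11a, Cldn10 and Zfp772 dim. In controls Glb1l3 (1.64 ± 0.32, adjusted p = 0.0839), Rab37 (0.90 ± 0.21) and Lca5 (-0.48 ± 0.13) changed the same way by over 0.5 of that amount without passing. Opn1sw in controls changed by -0.43 ± 0.25 (adjusted p = 0.533). The test of a different effect between ages gave an adjusted p of 0.363 for it over all genes. On simulated data that test recovered 15.5% of 2-fold and 48.5% of 4-fold differences. Among probe sets that were not dim, such as that of Opn1sw, it recovered 25.4% and 81.7%. A faster fall in knockouts was therefore neither shown nor excluded. At 4 against 2 months 8 genes passed, 5 higher and 3 lower. In both genotypes the age counts moved by over 1.5 times under most alternatives, between 1 and 177 in controls and between 0 and 154 in knockouts.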

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

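Of the tests in this part, those of strain segments, of the sex of the animals, of a lower share of photoreceptors, of the amount of pigment epithelium, of the 2 controls with low actin signal and of further probe sets among genes changed at least 2-fold were chosen after the results they address had been seen, and so were the alternatives without single pairs of arrays and with 1 sex per age. The tests of probe sequences over all called genes and of other splits were chosen before their results were seen.

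The first pattern was the 1022 genes that differed between genotypes over the mean of the ages, a number that no other of 100 splits of the genotypes within ages reached (1 of 100 with the real split, highest other 2), so that chance can be excluded. Sequence differences under single probe sets would give calls that a further probe set of the gene does not share. Of 423 genes with a further probe set that was not dim, 85.6% went the same way (95% interval 81.9% to 88.8%). That argues against the explanation as the general source of these calls. It cannot decide for single genes, since a direction can be shared by chance and 157 kept under 0.5 of the log2 fold. The rest of the 1022 genes could not be tested in this way. Among genes changed at least 2-fold it was 35 of 46 (76.1%, 61.2% to 87.4%), so that the explanation stays open for those as a set too. The larger number of females among the controls was argued against by the arrays of 1 sex per age, which left a median share of 1.03 of the log2 fold (quartiles 0.94 and 1.14), although their standard errors were 1.46 times as large and 290 of the 1022 genes were called there. Strain segments stay open as a candidate explanation for part of the genes: 92 pairs of called genes were neighbours on a chromosome, against a mean of 60.5 in 10000 draws matched on signal (p = 2e-04, permutation, one-sided) and 72 (mean of draws 58.8, p = 0.0427) and 74 (59.1, p = 0.0247) pairs among equally many top genes of the age comparisons. The excess was 31.5 pairs, of which the age comparisons, each within 1 genotype, reached 13.2 and 14.9. Chromosome 9 held 83 called genes where 56.5 were expected, and chromosome 3, which carries Rpe65, 51 against 51.4. Of the genes called at all 3 ages, chromosome 9 held 20 where 5.56 were expected. Chromosome 3 held 5 of them against 5.06, and chromosome 1 held 1 against 5.86. No run of 20 neighbouring genes on chromosome 3 held more than 1 of them. These counts gave no sign of a segment around Rpe65 rich in called genes, though they cannot exclude a small one.

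The second pattern was that photoreceptor lists were lower and glial lists higher in knockouts at the preset correlation. With an estimated correlation only the cone list passed. A lower share of photoreceptors would raise the genes of Müller glia and of inner retinal neurons alike, but the mean of 12 Müller glia genes (log2 0.33) lay 0.36 above that of 42 inner neuron genes (-0.04; p = 0.0288, permutation over genes, which are not independent). The medians were 0.33 and 0.03, and 12 of 12 and 25 of 42 genes lay above 0. The inner neuron genes spread widely (SD 0.52), with a mean below their median. The 2 controls with low actin signal were argued against as the source, since without them the smallest share of a list's median that was left over 5 lists was 0.799. A lower share of photoreceptors together with a change in the glia themselves stays open, as does a change of transcription within the cells; the effect of Rpe65 on either could not be told from these values and was not tested.

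The third pattern was the low Rpe65 signal. Less pigment epithelium in the knockout samples was argued against by the other pigment epithelium markers. Their median log2 difference was 0.99, toward the knockouts, while Rpe65 had -5.96, and none of the 13 passed on its own. That median was 0.41 without the 2 controls of low actin signal, 0.55 with log2(signal + 16) and 1.64 with sex as a covariate. Arrays of 1 sex per age cannot decide this, since at 2 months they kept only control retina 11. That retina was 1 of the 2 controls of low actin signal. Its mean log2 pigment epithelium signal, -3.39, was the lowest of all arrays. A loss of the transcript itself stays as a hypothesis, and which part of the gene the probe set reads was not known.

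A difference in the knockout effect between ages was seen for the following results. For Pttg1 the effect at 4 months minus that at 2 months was -4.43 (adjusted p = 0.00345 in the F-test for any difference between ages, lower in 3 of 3 knockouts than in all controls at both ages). For ganglion cell genes the median of that difference was 0.37 (adjusted p = 0.00326, and adjusted p = 0.771 with an estimated correlation), and for 6 minus 2 months it was 0.27 (0.0288 and 0.705). For circadian clock genes the difference between 4 and 2 months had a median of 0.38 (adjusted p = 0.00974, and adjusted p = 0.771 with an estimated correlation). For lens genes it was -3.29 (adjusted p = 0.000183, and adjusted p = 0.891 with an estimated correlation), and for 6 minus 2 months -2.81 (0.000393 and 0.705). Of these lists, no gene passed singly, and mean log2 lens signal was 1.51 and 5.22 in knockout retinas 2 and 3 at 2 months and -4.11 in retina 1. Signal also appeared outside the genes tested: 303 of 9160 probe sets without a gene name differed between genotypes over the mean of the ages (96 higher, 207 lower), and so did 42 of 932 with several names (16 higher, 26 lower).

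Splits of 6 arrays into 3 and 3 give 10, too few for a share under 0.05. The real split gave 260 genes at 2 months (1 of 10 splits gave as many, highest other 2), 222 at 4 months (1 of 10, highest other 1), 203 at 6 months (1 of 10, highest other 2), 15 with age in controls (1 of 10, highest other 2) and 18 with age in knockouts (1 of 10, highest other 1). For the list count of 11, 3 of 100 splits, the real split among them, gave as many, a share under the limit of 0.05 set beforehand. That argues against chance for the count. The margin was narrow, since the share rests on 100 sampled splits, the highest other gave 12 and with an estimated correlation only 1 list passed. Other splits also called lists at the preset correlation, some of them 8 or 10, so the count does not exclude chance for any single list. For the 1 gene with an effect that differed between ages, 46 of 100 splits gave as many and the highest other gave 62, so chance cannot be excluded; splits that mix the genotypes at some ages only turn the genotype effects themselves into differences between ages, a structure that such counts reflect.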

How the results depend on the processing

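The 6 alternatives named last were chosen after seeing the data; the others were chosen beforehand. No paired analysis was possible because the groups compared share no retina numbers; numbers 1, 2 and 3 occur at knockout 2 months and control 6 months, which were not compared. Of 162 results for named genes, no direction turned in any setting. Of the values, 4858 kept their side of the threshold, 1153 no longer passed and 3 newly passed. All of these results but Rpe65 at 4 months were chosen because they passed in the same arrays. A turned direction was therefore unlikely, and the other results could not newly pass. Of the counts under alternatives other than single arrays left out, 101 lay within 1.5 times and 65 did not. At the preset correlation, the cone, rod, shared photoreceptor, Müller glia, gliosis, antioxidant and glycolysis lists passed in 36 of 36 settings, the pigment epithelium list in 34, the lens list in 33, the immediate early list in 32 and the Y-linked list in 20 of 35. Signal limits what could be called: dim probe sets had a spread of 1.16 on the log2 scale. Except where fewer arrays, fewer genes or a stricter rule account for it by construction, the cause was not tested. The counts that moved were as follows, with 15 genes for age in controls and 18 for age in knockouts as the values to compare. Without the dimmest 40% of genes there were 364 genes at 4 months, 122 with age in controls and 114 with age in knockouts. A fit of only 6 arrays gives no value for the mean of the ages or the differing effect. The mean of all probe sets gave 5 with age in controls. Quantile normalization gave 32 with age in controls and 113 with age in knockouts, and centring 28 and 46. With only the 6 arrays compared there were 36 genes at 2, 10 at 4 and 26 at 6 months, 1 with age in controls and 0 with age in knockouts, by limma, whose unadjusted counts in the fit of all arrays were 2138 and 2160. The trended, robust prior gave 7 and 37 with age. Array weights gave 310 at 6 months and 59 and 111 with age. A 1.5-fold minimum gave 478 over the mean of the ages. Benjamini-Yekutieli gave 89, 80 and 69 at the 3 ages, 392 over their mean, and 2 and 4 with age. The lens covariate gave 112 at 6 months and 6 and 5 with age. The pigment epithelium covariate gave 136 at 4 months, 650 over the mean, and 7 and 5 with age. The sex covariate gave 151 at 2 months, 124 at 6 months, 574 over the mean, and 7 and 6 with age. With log2(signal + 16) there were 373 at 4 months and 97 and 115 with age. With an estimated correlation 1 list passed in place of 11. Without the 2 controls of low actin signal there were 165 at 2 months, 0 with an effect that differed between ages (831 at an unadjusted p in the fit of all arrays) and 6 with age in knockouts. Arrays of 1 sex per age (13 arrays, with 1 control at 2 months and 1 knockout at 6 months, each assumed to vary like the other groups) gave 130, 99 and 37 at the 3 ages, 377 over the mean, 5 with a differing effect, and 55 and 9 with age. Without the 2 knockouts of high lens signal there were 71 at 2 months, where 1 knockout was left, 618 over the mean, 2 with a differing effect and 8 with age in knockouts. A prior trended on signal gave 360 at 4 and 313 at 6 months, 3 with a differing effect, and 177 and 154 with age. The sex covariate on log2(signal + 16) gave 396 at 4 months and 32 and 49 with age. Quantile normalization of recovered signals gave 67 and 109 with age. Leaving out 1 array at a time gave 143 to 275 genes at 2 months, 119 to 218 at 4 months, 99 to 210 at 6 months, 817 to 1058 over the mean, 1 to 3 with a differing effect, 5 to 44 with age in controls, 5 to 34 with age in knockouts, and 9 to 11 lists. At 2 months the count was under 173 without knockout retina 2 (156), knockout retina 3 (146), control 11 (143) or control 9 (169); at 4 months without knockouts 31 (120) or 33 (119); at 6 months without knockouts 4 (129), 5 (129) or 6 (99) or control 1 (116).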

Other observations

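The list tests at single ages and between ages were added to the planned test over the mean of the ages and were singled out after their results were seen, as were the neighbouring genes; the other list values were planned. Over the mean of the ages, none of the lists of inner retinal neurons, immune cells and tissues other than lens and pigment epithelium passed, though single genes did. Among rod and ON bipolar genes (11 measured, median -0.02), 2 rose and 0 fell (3 and 0 adjusted over the list alone): Cabp5 (log2 0.56 ± 0.11) and the transcription factor Isl1 (0.28 ± 0.07, and 0.46 by a further probe set). Of 6 OFF bipolar genes (median 0.07) Neto1 rose (0.30 ± 0.08, and 0.18 by a further probe set; 1 higher and 1 lower adjusted over the list alone), and of 12 amacrine genes (median 0.06) the glycine transporter Slc6a9 rose (0.33 ± 0.07, and 0.58 by a further probe set; also 1 alone). Of 11 ganglion cell genes (median 0.00) the transcription factor Pou4f1 fell (-1.95 ± 0.27, and -0.10 by a further probe set; also 1 alone), and of 7 horizontal cell genes (median 0.00) 0 passed, also 0 adjusted over the list alone. Of 11 visual cycle genes other than Rpe65 (median 0.47), Rbp3 and the retinol dehydrogenase Rdh12 (-0.39 ± 0.06), both also photoreceptor genes, fell (2 higher and 2 lower adjusted over the list alone). In that list 2 genes passed as higher and 2 as lower with sex as a covariate, and 5 and 2 with that covariate on log2(signal + 16). With arrays of 1 sex per age its median was 0.63. The list shares genes such as Rrh with the pigment epithelium list. At 2 months the arrays of 1 sex kept only control retina 11, of the lowest mean log2 pigment epithelium signal (-3.39), so they cannot decide here. With sex as a covariate 0 amacrine and 0 OFF bipolar genes passed, and with 1 sex per age 0 ganglion cell and 0 rod and ON bipolar genes.

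Of 16 microglia genes (median 0.26, and 0.05 with log2(signal + 16), 0.05 with sex as a covariate and 0.13 without the 2 controls of low actin signal) the growth factor receptor Csf1r rose (log2 0.76 ± 0.20), of 12 antigen presentation genes (0.07) H2-D1 rose (0.43 ± 0.09, and 0.66 by a further probe set), of 15 interferon response genes (0.00) Irf7 fell (-0.46 ± 0.11), and of 13 apoptosis genes (0.05) the survival factor Bcl2 fell (-0.80 ± 0.13, and -0.41 by a further probe set), each also the only 1 adjusted over the list alone. Of 14 cholesterol synthesis genes (0.03) Sqle rose (0.45 ± 0.09) and Sc5d fell (-1.06 ± 0.09), of which a further probe set gave 0.14 (2 higher and 1 lower adjusted over the list alone). Of 40 oxidative phosphorylation genes (-0.04) Sdha fell (-0.23 ± 0.06), and of 13 clock genes (-0.07) Per3 fell (-0.28 ± 0.08, and -0.79 by a further probe set), each also the only 1 adjusted over the list alone. Of 10 vessel genes (-0.15) the receptor Kdr rose (0.69 ± 0.16) and the pericyte gene Rgs5 fell (-0.89 ± 0.12, and -0.31 by a further probe set), as they did adjusted over the list alone. Of 5 blood (0.01), 9 connective tissue (0.21), 8 muscle (-0.02) and 7 corneal epithelium genes (-0.36), 0 passed, also 0 adjusted over the list alone. With sex as a covariate 0 antigen presentation, interferon response, oxidative phosphorylation and clock genes passed, and 0 vessel genes as higher. The connective tissue median was -0.25 without the 2 controls of low actin signal and 0.55 with sex as a covariate, the corneal median -0.03 with log2(signal + 16), and the blood median -0.42 with sex as a covariate. Medians and means had opposite signs in the rod and ON bipolar, OFF bipolar, horizontal, ganglion, antigen presentation, interferon, apoptosis, cholesterol, blood and muscle lists.

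At single ages the cone list was lower with either correlation, with medians of -0.90, -1.15 and -1.29 and estimated-correlation adjusted p of 0.0239, 0.0170 and 0.00646. At 6 months the interferon list was lower (median -0.47, adjusted p = 0.00420, and adjusted p = 0.554 with an estimated correlation), led by Irf7 (log2 -0.92 ± 0.18); the test of a different effect between 6 and 2 months for that list gave an adjusted p of 0.0519. In controls at 6 against 2 months the same list was higher (median 0.78, adjusted p = 0.00396, and adjusted p = 0.728 with an estimated correlation), across arrays that also differ in overall signal. Mean log2 pigment epithelium signal was -3.39 and -3.36 in control retinas 11 and 9 at 2 months.

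Among genes called at all 3 ages, 3 pairs of neighbours were found. On chromosome 9, Abhd14a (log2 -2.74) lay beside Abhd14b (1.79), which went the other way, and Sorl1 (0.67, and 0.17 by a further probe set) beside Sc5d (-1.06). On chromosome 10, Ndufa12 (-0.94, and -0.62 by a further probe set) lay beside a gene model without a symbol (-3.32).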
